A study of Mus musculus with 143 samples.

How the data were processed

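The series holds 143 samples of mouse T cells from several assays, and this account covers the 3 libraries of its capSTARR-seq experiment: 2 RNA replicates and 1 input library, all from the T cell line P5424. The other 140 samples (chromatin immunoprecipitation, RNA-seq and chromosome conformation capture) were not analysed here. In capSTARR-seq, captured genomic fragments are cloned into a reporter so that a fragment with enhancer activity drives its own transcription, and activity is read as RNA over the input library. The labels list total RNA as the molecule of all 3 libraries, the input included, and whether the input was plasmid DNA is not given in the sources used here; each fold is over that library as deposited. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures or transfections, so the spread between these libraries may be technical. The p-values of tests per region measure only that spread. Those of the other tests treat regions as the unit within these libraries.

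The authors deposited 1 table per RNA replicate over the same 12897 regions. Per the file headers, each table gives the FPKM of the RNA library and the FPKM of the input library, that is, reads scaled to region length and library size. The deposited fold is a ratio that was recomputed as the RNA FPKM plus 1 over the input FPKM plus 1, with a largest difference of 4.8e-14. The deposited ratio was not centred. The authors also deposited an active or inactive class per replicate, named in the file headers after an inflexion point. The input values were identical in both tables, so a single input library stands behind both ratios. No input value lay below 1.06 FPKM, and whether regions had been filtered on input is not given in the sources used here. Bowtie2, TopHat2 and Bowtie 1.2.2 are named in the submitters' processing notes, without their roles, and the genome build named there is mm9. Region classes are named as the files name them, and what TSS_Random and Add_Ctl stand for, and in which cells the marks in the class names were measured, is not given in the sources used here.

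Of the 12897 regions, 12881 were 400 bp long and 16 were longer, up to 800 bp, and 378 overlapped another region. Among the 400 bp regions, 100% of FPKM values were whole multiples of the value of 1 read, within 0.1 reads, in each library. Depth was recovered from these steps and used only to describe precision. The values stayed in FPKM, so no count model was fitted. The gene name column was filled for 0 regions. The gene table at hand was of build GRCm38, and 54 regions on chromosome 7 and 22 on chromosome 8 lay past its last gene, so regions were not assigned to genes. The planned comparisons by gene list and at the loci studied by chromosome conformation capture were therefore not run, and the parts of the naming rule that rest on gene names did not apply.

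The choices that follow were made before the data were examined, except where stated. A region was called active when its deposited fold was at least 1.5 in both replicates, and strongly active at 3 or more in both. The moderated test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend), run on log2 of RNA over input with a pseudocount of 1 FPKM. The fit held only an intercept, so the mean trend is a trend on the tested log2 fold itself. The variance expected for a region therefore depends on the size and direction of its change. Each replicate was centred on the median of the Random class, the test was two-sided, and regions passed at a Benjamini-Hochberg adjusted p under 0.05 and a fold over the centre of at least 1.5. On this scale the change of a region with few reads is understated. Because the input is shared, its error enters both ratios and the limma p-values do not cover it. The test was checked on simulated data with the real regions and depths, 20 reads per molecule and 200 raised regions. With an error-free input it called 76% of 2-fold and 96% of 3-fold changes, and 0.118% of unchanged regions. With an input as noisy as the RNA it called 10% and 76%, and 1.21% of unchanged regions. The latter were 153 of 12697, beside 5, 38, 48 and 49 of 50 regions raised 2-, 3-, 4- and 6-fold. False calls thus outnumbered true ones, so with such an input the adjusted p did not hold the false share to 0.05. Lowered regions were not simulated, so the power to call them was not checked.

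Shares of active regions carry Wilson 95% intervals and were compared between each class and all others with two-sided Fisher exact tests, adjusted by Benjamini-Hochberg over the 7 classes. Comparisons of classes in pairs, odds ratios within 20 or 100 bins of input level (Cochran-Mantel-Haenszel) a logistic interaction of class with input, and the authors' class used as the call for class shares were chosen after the data had been seen. Differences in class medians were tested by two-sided permutation tests with 100000 resamples and given intervals from 2000 bootstrap draws. These tests of class medians were not part of the plan made before the data were examined. Regions are the unit in these tests and are not independent replicates. The intervals of shares, odds ratios and medians, and the limits, cover only the sampling of regions. They do not cover the error of the reads behind each region, and reads carry no molecular identifiers. Beside a count of 0, the limit that 3 counts would give is printed with the Wilson upper bound. The text names the 15 regions of highest mean log2 fold among those active in both replicates, and the 5 of lowest mean log2 fold, in each case with input above the lowest quintile of regions. Coordinates are those of the files, in mm9.

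Because both ratios share the input, unchanged regions were simulated 100 times against a redrawn shared input, once with the error of counted reads and once with the larger error seen between the RNA replicates. The spread per bin of input reads was simulated 200 times with 22.8 reads per molecule at every depth. The alternatives tried were other centres, pseudocounts, fold minimums and thresholds, a filter on low input, limma with other variance trends, single replicates, and, added after the data had been seen, a pseudocount of 0.1 for the named regions, the limma trend on input, overlapping regions left out, an input minimum of 100 reads and input level as a covariate (statsmodels 0.14.6). Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.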

Results

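The capSTARR-seq experiment measured the reporter activity of 12897 genomic regions in P5424 cells, a mouse T cell line, as RNA over input. The regions fell into 7 classes named in the files. There were 570 of Enh_K4me1, 2646 of Enh_K4me1_K27ac, 7600 of Enh_K4me1_K27ac_PolII, 1100 of Pro_K4me3_K27ac_PolII, 500 of TSS_Random, 478 of Random and 3 of Add_Ctl. The Enh and Pro prefixes are read here as enhancer and promoter, and the rest of each name as histone marks or RNA polymerase II. H3K4me1 is a mark found at enhancers, H3K4me3 at promoters and H3K27ac at active elements of both kinds. The regions held 8999732 reads in RNA replicate 1, 9583168 in replicate 2 and 7199798 in the input, as recovered from the FPKM steps. A region had a median of 308 reads in RNA replicate 1, 324 in replicate 2 and 298 in the input.

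The first question was how many regions drove transcription above their input. In both replicates, 1098 regions reached a fold of 1.5, which is 8.51% of all regions (Wilson 95% interval 8.04 to 9.01). A fold of 3 was reached in both by 127 regions, or 0.985% (0.828 to 1.17). Most regions lay below their input, with a median fold of 0.852 in replicate 1 and 0.862 in replicate 2. The Random class lay lower, at 0.657 and 0.679, and 6 of its 478 regions were active, or 1.26% (0.577 to 2.71). None of the 478 Random regions was strongly active, which allows a share of up to 0.628% by the limit of 3 counts, with a Wilson upper bound of 0.797%. Single replicates gave larger counts, 1751 regions at 1.5 in replicate 1 and 1881 in replicate 2, and at a fold of 3 they gave 164 and 202. The authors' deposited class called 543 regions in replicate 1 and 560 in replicate 2, and 348 in both. All 348 were among the 1098, which the thresholds fixed in advance. On the same deposited fold, the lowest value the authors called active was 2.12 in replicate 1 and 2.18 in replicate 2.

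Activity differed between region classes. Promoter-class regions (Pro_K4me3_K27ac_PolII) were active most often among the classes of over 3 regions, 185 of 1100 or 16.8% (14.7 to 19.1), against 7.74% of all other regions (adjusted p = 7.3e-20, Fisher exact test). This order was not seen at low input: in the lower 3 quintiles by input the promoter class stood at 5.10%, 7.59% and 7.07% and Enh_K4me1_K27ac_PolII at 8.48%, 8.36% and 7.57%. The promoter shares were 5 of 98, 6 of 79 and 7 of 99 regions. The intervals of the odds ratio between these 2 classes all included 1 (0.181 to 1.44, 0.315 to 2.11 and 0.356 to 2.05), so the order there is uncertain. TSS_Random followed at 72 of 500, or 14.4% (11.6 to 17.7), against 8.28% of the others (adjusted p = 1.2e-05). Its place rested on the highest input quintile. In the lower 4 quintiles it stood at 2.94%, 7.14%, 6.38% and 7.29%, each below Enh_K4me1_K27ac_PolII, which was at 7.77% in the last of these. Those TSS_Random shares were 1 of 34, 2 of 28, 3 of 47 and 7 of 96 regions. Their Wilson upper bounds were 14.9%, 22.6%, 17.2% and 14.3%, so they do not settle the order of the 2 classes. With input as a covariate the odds ratio of TSS_Random against the rest went from 1.86 to 1.40 and still passed. Enh_K4me1_K27ac_PolII held the most active regions, 673 of 7600 or 8.86% (8.24 to 9.51), and its share did not pass the test against the rest at 8.02% (adjusted p = 0.102). Enh_K4me1_K27ac was lower at 138 of 2646, or 5.22% (4.43 to 6.13), with adjusted p = 3.2e-12. Enh_K4me1 was lower at 21 of 570, or 3.68% (2.42 to 5.57), with adjusted p = 8.6e-06. The share in Random was below that of all others (adjusted p = 9.8e-12). In single replicates Enh_K4me1_K27ac_PolII did pass against the rest, at 14.4% in replicate 1 (adjusted p = 0.0012, Fisher exact test) and 15.3% in replicate 2 (adjusted p = 0.0042).

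**Figure D1:**
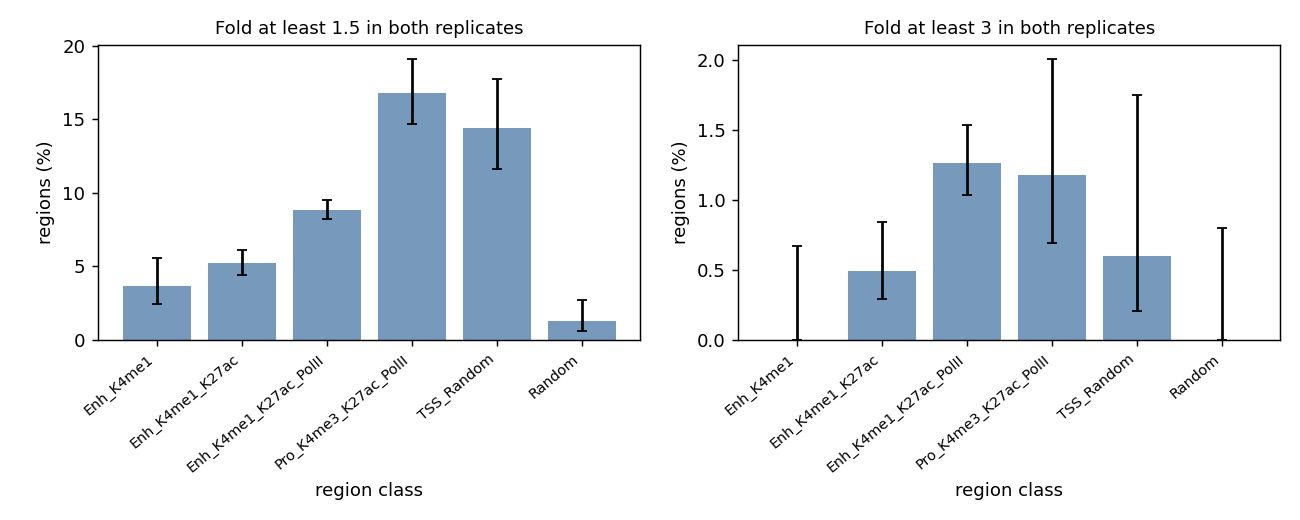
Share of regions in each class (percent of regions, bars from 0) with a fold over input of at least 1.5 (left) or at least 3 (right) in both replicates; lines are Wilson 95% intervals. The promoter class reached 16.8% on the left, and on the right it stood at 1.18% beside 1.26% for Enh_K4me1_K27ac_PolII.

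Among enhancer classes, activity was highest where RNA polymerase II was part of the class name. Enh_K4me1_K27ac_PolII was active more often than Enh_K4me1_K27ac (odds ratio 1.77, 95% interval 1.46 to 2.15, adjusted p = 1.6e-09 over 7 pairs, Fisher exact test). Within 20 bins of input level the odds ratio was 1.78 (1.47 to 2.15). It was also active more often than Enh_K4me1, with an odds ratio of 2.54 (1.63 to 4.17). The difference between Enh_K4me1_K27ac and Enh_K4me1 did not pass the test (odds ratio 1.44, 0.895 to 2.42, adjusted p = 0.159), nor did it within 20 bins of input (odds ratio 1.54, 0.961 to 2.47), although within 100 bins the interval lay above 1 (1.63, 1.01 to 2.63). Enh_K4me1 was active more often than Random, with an odds ratio of 3.01 (1.16 to 9.18, adjusted p = 0.024), a call that ended without the lowest input quintile (adjusted p = 0.081), with the authors' deposited class (4 of 570 against 0 of 478, adjusted p = 0.182) and at a fold of 3, which no region of either class reached.

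At a fold of 3 the promoter class no longer stood above the enhancer class with RNA polymerase II. Enh_K4me1_K27ac_PolII held 96 of the 127 strongly active regions, 1.26% of the class against 0.585% elsewhere (adjusted p = 0.00062, Fisher exact test). Enh_K4me1_K27ac and the promoter class held 13 each, 0.491% and 1.18% of their regions. Strongly active regions were found in 3 of 500 in TSS_Random and in none of the 570 of Enh_K4me1, which allows a share of up to 0.526% by the limit of 3 counts, with a Wilson upper bound of 0.669%. Against Enh_K4me1_K27ac_PolII the promoter class had an odds ratio of 2.08 at a fold of 1.5 (1.73 to 2.49, adjusted p = 4.2e-14) and of 0.935 at a fold of 3 (0.479 to 1.68, adjusted p = 1). Within 20 bins of input the odds ratio at 1.5 was 1.46 (1.18 to 1.79). With the authors' deposited class as the call it was 1.68 without bins (1.22 to 2.28, adjusted p = 0.0025, Fisher exact test). Within those bins it was then 1.09 (0.772 to 1.54), so both changes together ended the call. The difference between the promoter class and TSS_Random at a fold of 1.5 did not pass the test (odds ratio 1.2, 0.888 to 1.64, adjusted p = 0.240).

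Levels followed the shares. The median log2 fold of the promoter class lay 0.63 above that of Random (bootstrap 95% interval 0.56 to 0.71), that of TSS_Random 0.56 (0.48 to 0.64) and that of Enh_K4me1_K27ac_PolII 0.32 (0.27 to 0.38). Enh_K4me1_K27ac lay 0.23 above Random (0.18 to 0.30) and Enh_K4me1 0.22 (0.13 to 0.30). Each of these 5 differences had a permutation p of 1e-05, the smallest that 100000 resamples can give. The 3 Add_Ctl regions had mean log2 folds of 3.49 ± 0.06, 2.49 ± 0.02 and 1.36 ± 0.89 (SD, n = 2).

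Of the 15 most active regions, 13 were of the class Enh_K4me1_K27ac_PolII, 1 of Enh_K4me1_K27ac and 1 of Add_Ctl. Values are mean log2 fold over input ± SD over 2 RNA replicates. The SD leaves out the error of the shared input, and an SD of 2 values can be small by accident. It therefore understates the error of a fold, and the order of regions with close values is uncertain. The highest was the Enh_K4me1_K27ac region on chromosome 14, 32369125 to 32369524, at 3.79 ± 0.0021, where 336 input reads stood against 5792 and 6051 RNA reads. The Add_Ctl region on chromosome 1, 130487726 to 130488125, followed at 3.49 ± 0.06. The other 13 were of Enh_K4me1_K27ac_PolII, each 400 bp long. On chromosome 14, the region from 26336700 to 26337099 reached 3.42 ± 0.24 and that from 54846975 to 54847374 reached 2.97 ± 0.13. Chromosome 17 held a region from 52421625 to 52422024 at 3.29 ± 0.10. On chromosome 1, the region from 51641725 to 51642124 reached 3.20 ± 0.11 and that from 52207525 to 52207924 reached 2.84 ± 0.0030. Chromosome 13 held regions from 91680575 to 91680974 at 3.19 ± 0.13 and from 63629675 to 63630074 at 3.04 ± 0.06. The region on chromosome 18 from 61036875 to 61037274 reached 3.08 ± 0.02. On chromosome 9, the region from 57804625 to 57805024 reached 2.99 ± 0.08, and on chromosome 8 that from 114119725 to 114120124 also reached 2.99, ± 0.04. The remaining regions were on chromosome 7 from 89025725 to 89026124 at 2.97 ± 0.27, on chromosome 2 from 25321225 to 25321624 at 2.93 ± 0.17, and on chromosome 11 from 78816550 to 78816949 at 2.78 ± 0.06. All 15 passed the limma test, with adjusted p between 0.00022 and 0.0006.

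The 5 regions of lowest fold included 3 of Enh_K4me1_K27ac_PolII, 1 of Enh_K4me1_K27ac and 1 of Random. The order among them depended on the pseudocount, and values with 0.1 in place of 1 FPKM are given after each. The region on chromosome 11 from 68298775 to 68299174 had a mean log2 fold of -3.63 ± 0.48 (SD, n = 2), and -4.21 with 0.1. On chromosome 9, the region from 21113525 to 21113924 stood at -3.55 ± 2.19, with 0 RNA reads in replicate 1 and 126 in replicate 2 over 441 input reads, and at -5.25 with 0.1. The region on chromosome 4 from 100821875 to 100822274 had 0 and 4 RNA reads over 153 input reads, so its value of -3.49 ± 0.22 was set largely by the pseudocount, and it was -5.98 with 0.1. That on chromosome 2 from 30000175 to 30000574 stood at -3.35 ± 0.05, and at -3.77 with 0.1. The Random region on chromosome 8 from 24581161 to 24581560 stood at -2.97 ± 0.55, and at -3.49 with 0.1. None of the 5 passed the limma test, with adjusted p from 0.064 to 0.125. In that test the expected variance follows the tested log2 fold. The region on chromosome 2 was given a standard error of 0.767 despite its SD of 0.05. Failing this test therefore does not show that these regions are unchanged.

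Measured against the Random class, 3171 of the 12897 regions were more active by the limma test and 0 were less active. At an unadjusted limma p under 0.05, 4594 regions lay above the centre and 339 below it. All 1098 regions active in both replicates were among the 3171. The test called 40.8% of the promoter class, 36.6% of TSS_Random, 24.9% of Enh_K4me1_K27ac_PolII, 19.1% of Enh_K4me1_K27ac and 19.3% of Enh_K4me1. It also called 31 of the 478 Random regions, 6.49% (4.61 to 9.06); whether these are active was not tested. The counts rest on the centre. Against the median of all regions 1242 were more active and 7 less active, with 2742 above and 1458 below at an unadjusted limma p under 0.05. On the deposited scale, against the input, 488 were more active and 27 less active, and the unadjusted balance turned to 1805 above and 2623 below. Without the mean trend in limma there were 1498 more active and 149 less active, with the trend on input level 3102 and 516, and with a pseudocount of 0.1 FPKM 3058 and 37, so the count of 0 less active rests on these settings.

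The replicates were compared to see how reproducible the activity was. Log2 fold correlated across regions with Pearson r = 0.642 and Spearman rho = 0.641; regions are not independent replicates. Unchanged regions simulated against a shared input gave r = 0.531 with counting error alone and 0.530 with the larger error seen between the RNA replicates. The observed covariance was 0.436, and the simulated covariances were 0.00931 and 0.253. At a fold of 1.5 the 1098 shared regions compare with 255 for independent lists of these sizes, and at 3 the 127 compare with 2.57; part of the excess over independent lists may come from the shared input. The simulated unchanged regions gave a mean of 0.19 regions at 1.5 in both and 0 at 3 with counting error alone, and 565 and 87.4 with the larger error. The error of the single input library was not measured, and these simulations give it the error of the RNA libraries. They also redraw an input that already holds its own error. With the larger error the redrawn input could fall to 0 reads, while no region of the real input had fewer than 14. The 565 and 87.4 therefore do not estimate how many of the called regions are unchanged.

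The spread between replicates fell with depth. From the lowest to the highest quintile of regions by input, r was 0.434, 0.561, 0.683, 0.769 and 0.912. Unchanged regions simulated with the larger error in the RNA and the input gave 0.542, 0.520, 0.512, 0.513 and 0.509; with less error in the input these values would be lower. The SD of the log2 difference between replicates was 1.03, 0.80, 0.62, 0.49 and 0.32. In the lowest quintile, with a median of 79 input reads, 31.1% of regions differed by over 2-fold between replicates, against 0.659% in the highest, with a median of 1331. Over the 12606 regions with reads in both replicates the variance between replicates was 20.4 times that of counting reads, and over 20 bins by input reads the ratio ranged from 12.8 in the lowest to 39.2 in the highest.

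**Figure D2:**
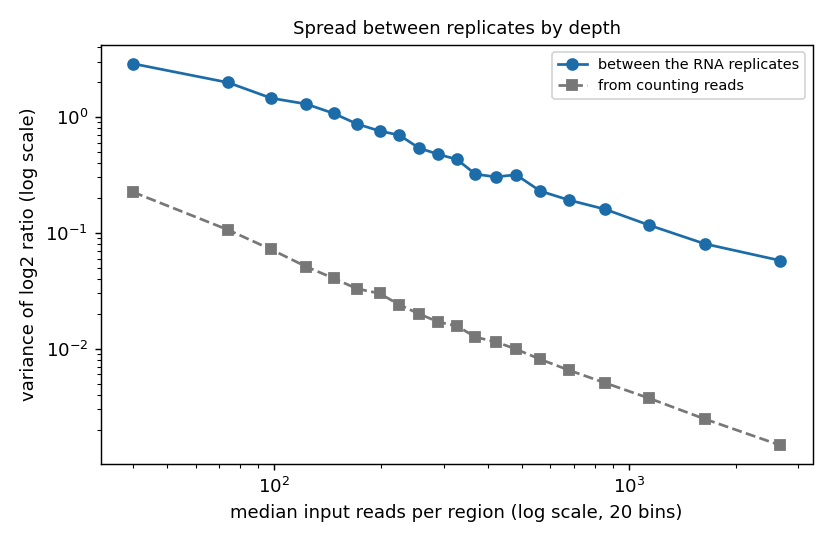
Variance of the log2 ratio between the 2 RNA replicates (circles) and the variance expected from counting reads (squares), over 20 bins of regions by input reads, both axes logarithmic. The variance between replicates fell from 2.87 at a median of 40 input reads to 0.0577 at 2664, above the counting line in every bin.

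Active shares were higher in the highest input quintile than in the lowest, with intervals that did not overlap, in the promoter class, TSS_Random and Enh_K4me1_K27ac_PolII. The share of active regions was 6.84%, 7.15%, 6.69% and 7.16% in the lower 4 quintiles by input and 14.7% (13.4 to 16.2) in the highest. In the promoter class it was 5.10% (2.20 to 11.4) in the lowest quintile and 22.2% (19.1 to 25.6) in the highest, and in TSS_Random 2.94% (0.521 to 14.9) and 20% (15.8 to 24.9). In Enh_K4me1_K27ac_PolII it was 8.48% (7.23 to 9.93) and 14.0% (12.0 to 16.3), in Enh_K4me1_K27ac 3.94% (2.66 to 5.80) and 7.49% (5.27 to 10.6), and in Enh_K4me1 5.45% (2.52 to 11.4) and 5.66% (2.62 to 11.8). Random stood at 1.14% in the lowest quintile and 0.741% in the highest. The highest quintile held 57.8% of the promoter class and 13.4% of Enh_K4me1_K27ac_PolII. Across all regions log2 fold had a Spearman rho of 0.078 with input and 0.024 with region length; within the promoter class rho with input was 0.329, within TSS_Random 0.288, within Enh_K4me1_K27ac_PolII 0.018 and within Random -0.126.

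**Figure D3:**
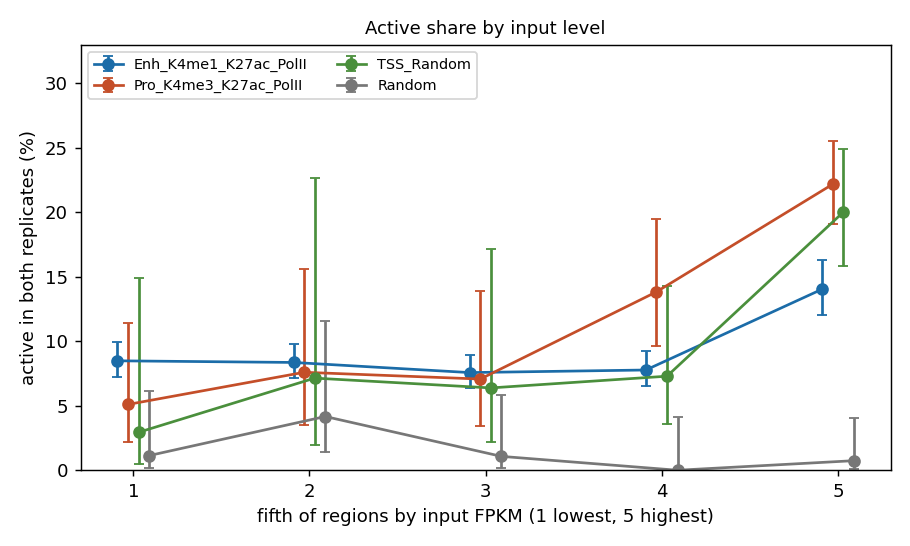
Percent of regions active in both replicates (fold of at least 1.5) by quintile of regions by input FPKM, for 4 classes, with Wilson 95% intervals. The promoter class and TSS_Random reached 22.2% and 20% in the highest quintile, and Random 0.741%.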

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

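The tests on overlapping regions, an input minimum of 100 reads, input as a covariate, input bins, limma trends on input, a pseudocount of 0.1 for named regions, class pairs and the authors' class as the call for class shares were chosen after the data were seen. No paired analysis was possible because the 2 RNA replicates share 1 input library and no second group carries replicate numbers. A limma test without either replicate leaves no residual degrees of freedom and was not run; comparisons by gene list and at the loci of the conformation capture were not run either. Of the 55 alternatives for class shares, 47 kept direction and side of the threshold, as did 58 of 62 for class pairs. A further 8 for class pairs gave no odds ratio, because a class had no called region; of the 6 with a Fisher exact test, 3 lost their call, Enh_K4me1 against Random at a fold of 3 and with the authors' call, and TSS_Random against Random at a fold of 3 (3 of 500 against 0 of 478, adjusted p = 0.437). With a pseudocount of 0.1, 12 of 22 named regions moved by no more than their SD and 10 moved further; with single replicates 0 changed sign, and their distance from a mean of 2 values cannot exceed the SD.

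The number of regions more active than the centre in limma went from 3171 to 488 on the deposited scale, to 1242 with the centre at the median of all regions and to 1498 without the mean trend. The number active in both replicates went from 1098 to 450 at a fold of 2, to 360 at the inflexion point, to 348 with the authors' call and to 1756 with folds divided by the median; single replicates gave 1751 to 1881. The strongly active went from 127 to 58 at a fold of 4 and to 209 with folds divided by the median, and single replicates gave 164 to 202. Moving the limma centre changed what regions are compared with, at the same cut-offs. Leaving out the mean trend changed the expected variance, which otherwise follows the tested log2 fold itself. How that trend moves the count was not tested. The other shifts follow from stricter or looser thresholds. The replicate r was 0.721 without the lowest input quintile and 0.625 among regions with a mean fold of at least 1.5.

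The share of Enh_K4me1_K27ac_PolII passed the test against the rest at a fold of 3 (1.26%), in single replicates (14.4% to 15.3%), without overlapping regions (8.79%), with the authors' call (3.04%) and with input as a covariate (odds ratio 1.28); the cause was not tested. At a fold of 3 the promoter class no longer passed (1.18%), TSS_Random fell below the rest (0.60%, not past the test) and the odds ratio of the promoter class against Enh_K4me1_K27ac_PolII turned to 0.935; the cause was not tested. With the authors' call within 20 bins of input, that odds ratio was 1.09 and no longer passed. Enh_K4me1 against Random no longer passed without the lowest input quintile (odds ratio 2.60), and Enh_K4me1_K27ac against Enh_K4me1 passed within 100 bins of input (1.63) but not within 20 (1.54); the cause was not tested. Depth limits single regions: in the lowest input quintile, replicates differed by over 2-fold in 31.1% of regions.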

Other observations

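The tests of the spread between replicates and of promoters against enhancers, and the counts of low regions, of chromosomes and of neighbours that do not overlap, were chosen after the results were seen; the other tests of neighbours were set beforehand. Regions at 0.333 of their input or less in both replicates numbered 171. They made up 2.72% of Random (13 of 478, Wilson 95% interval 1.60 to 4.60, adjusted p = 0.045, Fisher exact test) and 0.545% of the promoter class (6 of 1100, 0.250 to 1.18, adjusted p = 0.045). Without the lowest input quintile 102 such regions were left; Random stayed above the rest at 2.56% (adjusted p = 0.036, Fisher exact test), and the promoter class no longer passed at 0.299% (adjusted p = 0.060). Single replicates gave 653 to 689 such regions. No chromosome passed the test for its share of active regions against the rest; the lowest adjusted p, 0.0525, was that of chromosome 14, at 4.67% (3.05 to 7.11).

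The replicates differed by 20.4 times the variance of counting reads. The variance fell with input reads with a slope of -1.01 on log scales (95% interval -1.05 to -0.962), which is consistent with reads that are copies of fewer independent molecules, and amplification and a limited number of transfected plasmids both stay open as sources of such copies. The same number of copies at every depth was simulated with no other variance between the libraries. In the bin of most input reads the ratio was 39.2, above the simulated 20.6 to 25.6, while in the bin of fewest it was 12.8 against a simulated 12.7. Such copies alone therefore did not give the ratio at high depth. A further variance between libraries that is the same at every depth was not simulated, so whether the number of copies changes with depth stays open. In the lowest input quintile the covariance between replicates was 0.405, against 0.670 simulated with the RNA error also in the input. The simulated input could fall to 0 reads, while no region of the real input had fewer than 14. This gap therefore cannot show how much error the input carries. No biological explanation was tested.

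Promoter-class regions were active more often than Enh_K4me1_K27ac_PolII regions at a fold of 1.5. More input reads behind promoters are argued against as the whole cause by an odds ratio of 1.46 within 20 bins of input (1.18 to 1.79), although with the authors' call the same odds ratio was 1.09 (0.772 to 1.54). From the lowest to the highest input quintile the odds ratio was 0.580 (0.181 to 1.44), 0.901, 0.929, 1.90 and 1.74 (1.34 to 2.28), and it grew by a factor of 1.31 per doubling of input (1.15 to 1.5, p = 4.5e-05, logistic interaction) but with the authors' call by 1.11 (0.899 to 1.37, p = 0.331). A uniform gain of promoters at every input level stays open. The 98 promoter regions of the lowest quintile were few, and the interval of their odds ratio, 0.181 to 1.44, includes values above 1. How the larger error at low input moves this odds ratio was not tested. A biological difference between promoters and enhancers in this assay stays open and was not tested.

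Active regions lay near other active regions: 81 of the 424 active regions with a neighbour within 10 kb had an active one. Class and input level of neighbours are argued against as the whole cause, since calls permuted within class and input quintile gave 32 to 69 in the middle 95% of 10000 draws. With neighbours under 1 kb left out, the count was 25, inside the permuted range of 22 to 55, and for all neighbours that do not overlap it was 35, inside 29 to 66. The pattern is therefore consistent with overlapping regions that share reads, and no excess of active neighbours was detected beyond them; no biological explanation was tested.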
